A study of Homo sapiens with 8 samples.

How the data were processed

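Total RNA from 2 human pancreatic cancer cell lines, MiaPaCa and L3.6pl, was hybridised to Affymetrix PrimeView arrays, which measure each gene with 1 or more sets of short 3'-weighted probes. Per the labels' protocols, cells were grown in DMEM with fetal bovine serum and received 500 nM JQ1 or the solvent DMSO for 24 h, and RNA was extracted with a column kit. Each line had 2 DMSO and 2 JQ1 samples, so that 8 arrays fell into 4 groups of 2. The group and the replicate number of each array came from its title in the labels. The labels do not say whether the replicates of a group were separate cultures, so p-values of single genes rest on the spread between these samples, which may be technical. The p-values of overlaps between lines and of camera, described below, compare genes with one another and inherit this limit.

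The deposited values are log2 signals made by the authors with RMA (robust multi-array average), per the submitters' processing notes and the column headers, with no version given in the sources used here. RMA corrects background, makes the distributions of the arrays it is run on alike and summarises the probes of a set. A table of all 8 arrays and 2 tables of 1 line each held 49395 probe sets and equal values (largest difference 0.0 log2 units, after rounding to 6 decimals). The sorted values of arrays of different lines lay 0.254 to 0.273 log2 units apart on average, against 0.0103 to 0.0671 for arrays of 1 line, so the lines appear to have been normalized separately. Differences between JQ1 and DMSO were therefore tested within each line, the lines were compared through these differences, and no test was run between DMSO-treated lines, although one had been planned. Because RMA gives the arrays of a line like distributions, a change in the total amount of mRNA per cell cannot be seen in these values.

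Gene symbols were those of the deposited tables. Of the 49395 probe sets, 102 were array controls, 436 had no symbol, 1994 had several and 46863 had 1. A spreadsheet had turned the symbols of 86 probe sets into dates, and 80 of these were restored from the gene title. Of 18833 symbols, 17605 are current in the RefSeq gene table of assembly GRCh38.p14 and 998 matched 1 gene by an older name. Symbols are given as deposited, including older histone names such as HIST1H2BC. The gene table served only for names and for the order of neighbouring genes, and no coordinates are given because no build was named in the sources used here. Each gene was represented by its probe set with the highest mean over the 8 arrays. Among the 12195 genes with more than 1 probe set, 253 had probe sets called in opposite directions under JQ1 in MiaPaCa and 247 in L3.6pl.

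A linear model with 4 group means was fitted to the log2 values of all 18833 genes with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 4 residual degrees of freedom), without a filter on dim genes. Contrasts were JQ1 minus DMSO in each line and the L3.6pl response minus the MiaPaCa response, called the difference between lines. All adjusted p-values are Benjamini-Hochberg values within a contrast, and a gene was called below 0.05. Errors beside log2 changes are the fitted standard errors with n = 2 arrays per group, and errors beside levels are standard deviations over 2 arrays. Overlaps of calls between lines were compared with independent lists and tested with Fisher's exact test, two-sided. The 2 responses rest on different DMSO arrays.

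The 25 gene lists were fixed before the data were examined, as were the tests, the settings tried and the rule for named genes. Lists covered BET and P-TEFb genes, polyadenylated histone genes, MYC targets, squamous and classical subtype genes, transcription factors, the KDM6A complexes, 2 cell cycle phases, p53 targets, apoptosis, inflammatory and interferon genes, epithelial and mesenchymal genes, YAP and MAPK outputs, lysosome, cholesterol, ATF4, hypoxia and ribosomal genes, and markers of stromal, immune and other pancreatic cells. They were tested with limma's camera with the inter-gene correlation preset to 0.01, and again with a correlation estimated per list. limma's fry was run as an alternative. Fry's directional test asks whether a list moves one way on balance and its mixed test whether members change in either direction, and neither compares a list with other genes. Named genes were the 10 largest rises and 10 largest falls per line with both JQ1 arrays on one side of both DMSO arrays (passing over LOC, uncharacterized, antisense and pseudogene symbols), the 5 strongest shared rises and falls, the 5 largest differences between lines in each direction, 9 genes fixed in advance, and for each list up to 4 members with the smallest adjusted p among those past the threshold. The part of the rule on DMSO-treated lines was not used, as that test was not run. Fewer were named in places, in the order of the rule, and some genes that the rule names are not reported here.

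The array's background probe sets gave a bound for dim signals, taken as the level of the control set for probes with 17 G or C bases. Averaged over 2 DMSO arrays this bound was 4.27 in MiaPaCa and 3.64 in L3.6pl. A gene whose chosen probe set lies at or below it is called below the bound and has no measurable level there, and a fold change to or from such a level is a lower limit of the true change. The number of arrays limits the precision. On simulated data of 18833 genes with the spread of these arrays, 49.3% of genes changed by 0.5 log2 units, 92.5% changed by 1 and 98.5% changed by 2 were called for JQ1 in MiaPaCa. For JQ1 in L3.6pl the shares were 59.7%, 94.0% and 100%, and for the difference between lines 7.46%, 83.6% and 97.0%. Of the calls on simulated data, 4.76%, 5.06% and 7.41% were false for JQ1 in MiaPaCa, JQ1 in L3.6pl and the difference. Only 66 or 67 genes were changed at each size, far fewer than were called in the data. The adjustment of p-values was therefore stricter in the simulation, and these shares need not hold for the results below.

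Alternatives were a replicate block, the 4 arrays of a line alone, eBayes with trend and robust settings, 2 filters on dim genes, the mean of all probe sets of a gene, every probe set on its own, quantile normalization of all 8 arrays, centring on the median, the per-line tables, a threshold of 1 log2 unit and leaving out each array. A setting without probe sets whose suffix marks possible cross-hybridization (_s_at or _x_at) was added after seeing the data. Gene Ontology terms from the deposited annotation were also tested with camera, as an exploration. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9 read the tables and drew the figures.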

Results

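Expression was profiled on 8 arrays from 2 human pancreatic cancer lines treated with JQ1, a small molecule that displaces BET bromodomain proteins from acetylated chromatin. MiaPaCa is a line of poorly differentiated pancreatic carcinoma cells, and L3.6pl is a metastatic variant derived from another pancreatic carcinoma line. Each line contributed 2 arrays with DMSO and 2 arrays with 500 nM JQ1 for 24 h. The series concerns KDM6A, an X-linked demethylase of histone H3 lysine 27 that acts with COMPASS-type methyltransferases. The arrays of a group correlated with r of 0.9975 to 0.9978 across probe sets, DMSO and JQ1 arrays of 1 line with r of 0.9814 to 0.9837, and arrays of different lines with r of 0.8858 to 0.9091. Genes are not independent replicates, so these r values describe similarity only. Median signals lay between 5.36 and 5.59 log2 units on the 8 arrays.

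The gene that names the series, KDM6A, had a level of 2.87 ± 0.11 log2 units in DMSO-treated MiaPaCa (SD, n = 2), which lay -1.40 log2 units from the background bound. In DMSO-treated L3.6pl its level was 7.98 ± 0.11 (SD, n = 2), 4.34 units above the bound there. Both probe sets for KDM6A showed this pattern. RUNX3, a runt-domain transcription factor, and GATA6, a factor of the classical pancreatic lineage, were also below the bound in MiaPaCa with their chosen probe sets, with levels of 3.63 and 2.96, and stood at 10.00 and 6.13 in L3.6pl. Of 4 RUNX3 probe sets, 1 with a cross-hybridization suffix read 5.35 in MiaPaCa, above the bound, and 6.13 in L3.6pl. TP63, a factor of squamous epithelium, was above the bound in both lines with its chosen probe set, at 8.65 in MiaPaCa and 10.32 in L3.6pl. Its other probe sets read 5.92, 4.58, 4.34 and 4.30 in DMSO-treated MiaPaCa, where the bound was 4.27. Among markers chosen after their values were seen, VIM, a mesenchymal filament, had 14.31 in MiaPaCa and 10.43 in L3.6pl. The epithelial genes CDH1 and EPCAM had 3.29 and 2.74 in MiaPaCa and 10.04 and 12.73 in L3.6pl. The lines appear to have been normalized separately, so these levels were set side by side without a test.

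JQ1 in MiaPaCa raised SERPINI1, which encodes the protease inhibitor neuroserpin, and a block of histone genes, and lowered TM4SF18. SERPINI1 rose 16.9-fold (log2 change 4.08 ± 0.16 SE, n = 2 arrays per group, adjusted p = 5.10e-06) from a level below the background bound. HIST1H2BD rose 12.99-fold, HIST1H3H 12.9-fold and HIST1H2BC 12.5-fold, followed by HIST1H2AC, HIST1H2AG, HIST1H2AD and HIST1H2BJ at 6.45-fold to 6.82-fold. The HIST1H2BJ probe set without a cross-hybridization suffix read 0.15 log2 units, and HIST1H2BC and HIST1H2AC had only probe sets with such a suffix. The HIST1H2BD value came from a probe set without such a suffix, and another without it read 3.12 log2 units. ITPR1, a calcium release channel of the endoplasmic reticulum, rose 6.27-fold and PPP3CA, a catalytic subunit of calcineurin, 5.97-fold. TM4SF18, a tetraspan membrane protein, fell 43.7-fold (log2 change -5.45 ± 0.11 SE, n = 2 arrays per group, adjusted p = 2.14e-06).

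SEMA3D, a secreted semaphorin, fell 11.1-fold and PDE10A, a phosphodiesterase of cyclic nucleotides, 10.6-fold. CCDC190 fell 8.54-fold and the homeobox gene HOXC8 8.41-fold. HNMT, which methylates histamine, fell 8.01-fold, and GLDC, the glycine decarboxylase of the glycine cleavage system, fell 7.97-fold. GSAP, ABCC2 and ANO1, the last a calcium-activated chloride channel, fell 7.04-fold, 6.90-fold and 6.89-fold. SERPINI1 and HIST1H2AD started below the background bound and SEMA3D, GLDC and GSAP ended below it, so their folds are lower limits. Over all genes, 7049 of 18833 (37.4%) were called, of which 3518 rose and 3531 fell. With a change of at least 1 log2 unit, 371 rose and 768 fell.

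Among the genes fixed in advance, KDM6A (0.15 ± 0.11 SE) and GATA6 (0.10 ± 0.11 SE) did not pass the test in MiaPaCa and both were below the background bound. MYC rose by 0.26 ± 0.07 SE log2 units (n = 2 arrays per group, adjusted p = 0.0188). HEXIM1, which encodes an inhibitor of the elongation kinase P-TEFb, rose 1.70-fold (0.77 log2 units, or 0.39 to 0.73 with its 4 other probe sets), and the cell cycle inhibitor CDKN1A rose 3.23-fold. TP63 fell 3.07-fold (log2 change -1.62 ± 0.08 SE). Its other probe sets, most of them near the bound, read -1.05, -0.43, -0.16 and -0.059. Those with -0.16 and -0.059 did not pass when every probe set was tested on its own. RUNX3 had a change of 0.28 ± 0.08 SE that passed the test, with its chosen probe set below the background bound. The RUNX3 probe set above the bound read 0.16, which did not pass.

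Of the 25 lists, 6 passed camera in MiaPaCa. Of 14 measured polyadenylated histone genes, 13 rose and 0 fell, with a median of 2.003 log2 units (adjusted p = 1.28e-09, or adjusted p = 0.169 with an estimated correlation). HIST1H2BD and HIST1H2BJ had the smallest adjusted p of this list, and adjusted over the list alone 13 rose and 1 fell. Of the 10 probe sets of this list without a cross-hybridization suffix, 6 rose. Lysosome and autophagy genes were shifted up, with 21 of 44 risen and 7 fallen, or 23 and 7 adjusted over the list alone (adjusted p = 0.0322, or adjusted p = 0.469 with an estimated correlation). The autophagy adaptor SQSTM1 rose 2.18-fold and MAP1LC3B, a marker of autophagosomes, 1.82-fold. MYC targets were shifted down, with 24 of 59 fallen and 8 risen, or 25 and 8 adjusted over the list alone (adjusted p = 0.0169, or adjusted p = 0.469 with an estimated correlation). In this list the cyclin-dependent kinase CDK4 fell 1.95-fold and BYSL, a ribosome assembly factor, 1.77-fold.

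Mesenchymal and EMT genes were shifted down in MiaPaCa, with 12 of 33 fallen and 2 risen, or 14 and 2 adjusted over the list alone (adjusted p = 0.00728, or adjusted p = 0.234 with an estimated correlation). The collagen gene COL4A2 fell 2.14-fold and the myosin light chain MYL9 1.85-fold. Of 29 hypoxia and glycolysis genes 12 fell and 5 rose, or 14 and 7 adjusted over the list alone (adjusted p = 0.0322, or adjusted p = 0.469 with an estimated correlation). PDK1, a kinase that restrains pyruvate dehydrogenase, fell 2.81-fold and PFKFB4, a regulator of glycolysis, 3.23-fold. Of 41 cytosolic ribosomal protein genes 7 fell and 0 rose, with a median of -0.11, or 3 and 0 adjusted over the list alone (adjusted p = 0.00728, or adjusted p = 0.620 with an estimated correlation). RPL3 and RPL14 fell by 0.32 and 0.31 log2 units, but the RPL3 probe set without a cross-hybridization suffix read 0.48.

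The other 19 lists did not pass in MiaPaCa (adjusted p from 0.0744 to 0.937). Of 30 epithelial junction and keratin genes 9 fell and 2 rose, and of 14 BET and P-TEFb genes 7 rose and 2 fell, among them BRD2 with a 2.44-fold rise. Of 28 p53 targets and CDK inhibitors 12 rose and 7 fell, with the smallest adjusted p for the p53 target TP53I3, which rose 2.93-fold. Of 38 DNA replication and S-phase genes 14 fell and 10 rose, with CLSPN up 2.52-fold and E2F2 and POLE2 down 2.34-fold and 2.15-fold. Of 34 G2 and mitosis genes 14 rose and 7 fell, although FOXM1, a factor that drives mitotic genes, fell 2.79-fold. Of 34 inflammatory genes 8 rose and 7 fell, with NFKBIZ up 4.07-fold and the cytokine LIF down 2.73-fold.

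In MiaPaCa 5 of 34 squamous genes rose and 4 fell, TP63 and the keratin KRT15 (4.96-fold) among the fallen, and 1 of 34 classical progenitor genes rose and 2 fell. Of 29 lineage transcription factors 8 rose and 6 fell, with the epithelial ETS factor EHF down 3.52-fold. For KDM6A, COMPASS and Polycomb genes the counts were 5 risen and 6 fallen of 25, for apoptosis regulators 8 and 5 of 24, and for interferon-stimulated genes 6 and 7 of 41. YAP and TEAD targets had 9 risen and 3 fallen of 23, MAPK output genes 7 and 8 of 22, cholesterol genes 7 and 5 of 24, and ATF4 genes 6 and 9 of 27. Of 21 stromal and endothelial markers 1 rose and 3 fell, with COL1A2 down 2.74-fold, and of 22 immune markers 1 rose and 4 fell. Of 19 acinar and endocrine markers 1 rose and 0 fell. Adjusted over the list alone, the counts of these 19 lists moved by at most 2 genes. Median, mean and test differed in sign for 10 lists, namely squamous, classical, transcription factor, KDM6A complex, interferon, MAPK, cholesterol, ATF4, stromal and immune genes.

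The lysosome call in MiaPaCa was lost without MiaPaCa_DMSO replicate 2 (adjusted p = 0.0643) or MiaPaCa_JQ1 replicate 1 (adjusted p = 0.0834), and the hypoxia call without MiaPaCa_JQ1 replicate 2 (adjusted p = 0.0679). A filter on dim genes ended the MYC target, lysosome and hypoxia calls, and leaving out probe sets with cross-hybridization suffixes ended the mesenchymal, hypoxia and ribosomal calls.

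**Figure D1:**
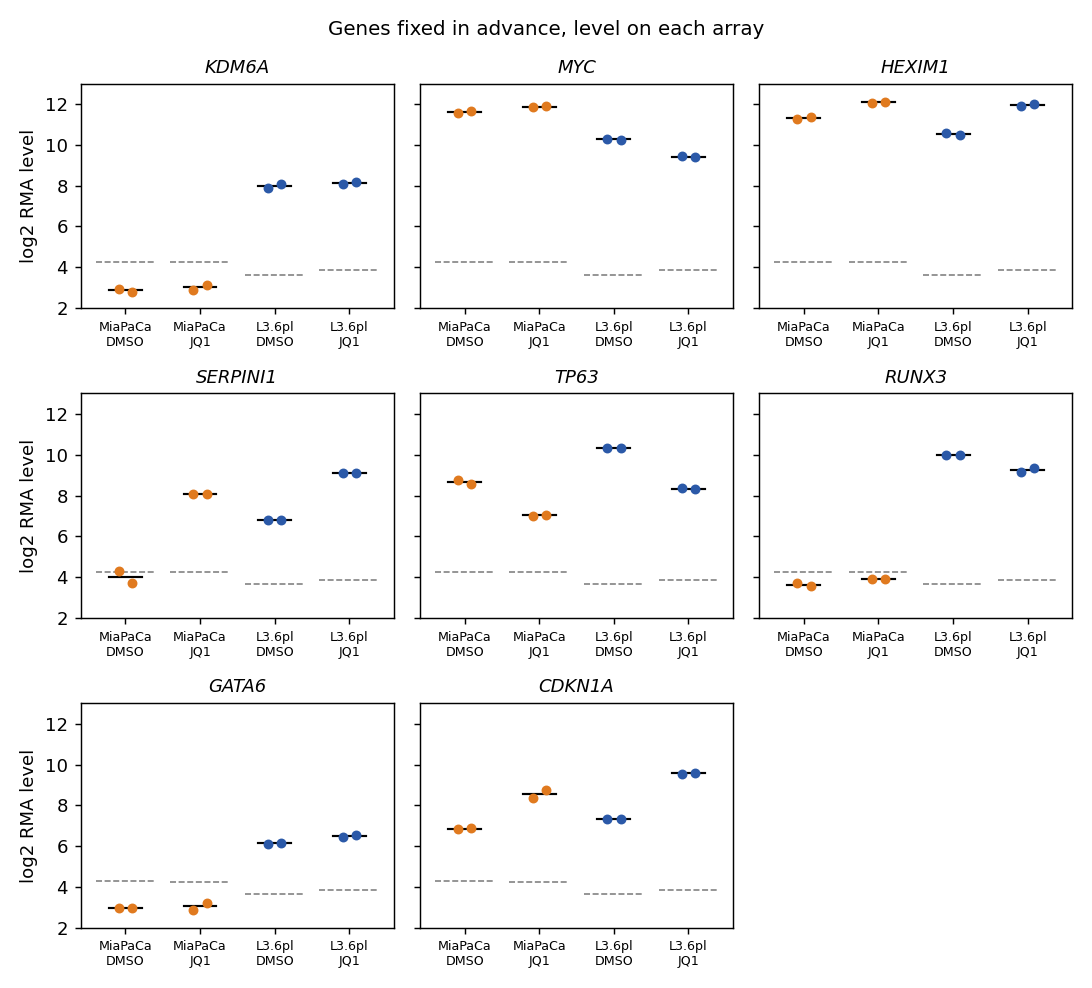
Log2 RMA level (y axis) of 8 genes fixed in advance on each of the 8 arrays, by line and treatment (x axis). Points are arrays, solid bars are means of 2 arrays and dashed lines are the background bound of the group. KDM6A lies below the bound in MiaPaCa and above it in L3.6pl, and the lines appear to have been normalized separately.

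JQ1 in L3.6pl raised PAG1, a membrane adaptor of the kinase CSK, together with histone genes, and lowered CLDN20 and TENM2. PAG1 rose 9.24-fold (log2 change 3.21 ± 0.10 SE, n = 2 arrays per group, adjusted p = 3.11e-06). HIST1H2BC rose 7.03-fold, HIST2H2BE 6.47-fold, HIST1H2AE 5.50-fold and HIST1H2AG 5.18-fold, while another HIST2H2BE probe set read 0.28 log2 units. CLDN20, a claudin of tight junctions, fell 40.3-fold (log2 change -5.33 ± 0.12 SE, n = 2 arrays per group, adjusted p = 1.66e-06). TENM2, a teneurin adhesion protein, fell 30.5-fold.

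EFR3B rose 5.99-fold, DNAJC6, the uncoating factor auxilin, 5.90-fold, and TRIM36, a ubiquitin ligase, 5.80-fold. ARHGAP29, a GTPase-activating protein, rose 5.58-fold and FAM46C, a non-canonical poly(A) polymerase, 5.38-fold. TMEM100 fell 15.3-fold, GSAP 13.8-fold and TPRG1 10.5-fold. NPR3, the clearance receptor of natriuretic peptides, fell 10.5-fold, and SCG2, a secretory granule protein, 10.3-fold. EHF fell 9.56-fold and CEMIP, which takes part in hyaluronan breakdown, 9.53-fold. FAM46C started below the background bound and CLDN20 and GSAP ended below it, so their folds are lower limits. In MiaPaCa, PAG1 rose by 0.85 log2 units at levels below the bound, and its probe sets without a cross-hybridization suffix read -0.042. Over all genes, 7738 of 18833 (41.1%) were called, of which 3996 rose and 3742 fell. With a change of at least 1 log2 unit, 227 rose and 680 fell.

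In L3.6pl, MYC fell 1.79-fold (log2 change -0.84 ± 0.07 SE, n = 2 arrays per group, adjusted p = 9.05e-05), and RUNX3 fell 1.69-fold. TP63 fell 3.96-fold (log2 change -1.99 ± 0.08 SE). Its other probe sets read -1.89, -1.66, -0.94 and -0.14, and the one with -0.14 did not pass when every probe set was tested on its own. HEXIM1 rose 2.76-fold, SERPINI1 4.97-fold and CDKN1A 4.74-fold. GATA6 rose 1.30-fold. KDM6A, at 0.14 ± 0.11 SE log2 units, did not pass the test (adjusted p = 0.350).

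Of the 25 lists, 5 passed camera in L3.6pl. MYC targets were shifted down, with 42 of 59 fallen and 1 risen, the same numbers adjusted over the list alone, and a median of -0.37 (adjusted p = 3.30e-11, or adjusted p = 0.0985 with an estimated correlation). PPRC1, a coactivator of mitochondrial biogenesis, fell 1.99-fold and the folate carrier SLC19A1 2.10-fold. SORD, which encodes sorbitol dehydrogenase, fell 1.96-fold, but its probe set without a cross-hybridization suffix read 0.028 log2 units. Of 38 DNA replication and S-phase genes 22 fell and 2 rose, or 24 and 3 adjusted over the list alone (adjusted p = 2.84e-06, or adjusted p = 0.0985 with an estimated correlation). E2F2, an S-phase transcription factor, fell 3.10-fold and POLE2, a subunit of DNA polymerase epsilon, 2.84-fold.

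Of 14 polyadenylated histone genes 12 rose and 0 fell in L3.6pl, also adjusted over the list alone, with a median of 1.23 (adjusted p = 2.49e-08, or adjusted p = 0.0985 with an estimated correlation). By adjusted p, HIST2H2BE and HIST1H2BD (4.81-fold) came first in this list. Of its 10 probe sets without a cross-hybridization suffix, 5 rose. Lysosome and autophagy genes were shifted up, with 23 of 44 risen and 4 fallen, or 24 and 5 adjusted over the list alone (adjusted p = 0.0109, or adjusted p = 0.202 with an estimated correlation). The lysosomal genes LAMP3 and NEU1 rose 3.43-fold and 2.58-fold. Of 28 p53 targets and CDK inhibitors 15 rose and 5 fell, or 16 and 5 adjusted over the list alone (adjusted p = 0.0369, or adjusted p = 0.202 with an estimated correlation). CDKN2B, an inhibitor of CDK4 and CDK6, rose 3.52-fold and the polo-like kinase PLK2 2.42-fold. The p53 list lost its call without L3.6pl_JQ1 replicate 1 (adjusted p = 0.0573).

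The other 20 lists did not pass in L3.6pl (adjusted p from 0.0603 to 0.970). Of 34 squamous genes 10 fell and 5 rose, with the desmosomal cadherin DSG3 down 8.35-fold. The squamous list did pass as fallen with some alternatives, among them the mean of all probe sets of a gene (adjusted p = 0.0228). Of 34 inflammatory genes 12 fell and 5 rose, with the chemokine CXCL3 down 5.01-fold and LIF down 5.05-fold. Of 41 interferon-stimulated genes 16 fell and 6 rose, with PARP9 down 6.48-fold and IFI44 down 3.27-fold. Of 33 mesenchymal genes 14 fell and 8 rose, with COL4A1 down 2.85-fold and the receptor kinase AXL 6.76-fold. The mesenchymal list did pass camera as fallen with some alternatives, among them quantile normalization of all arrays (adjusted p = 0.0494). Of 29 hypoxia and glycolysis genes 9 rose and 5 fell, with the enolase ENO2 (2.06-fold up) and the vasoactive peptide gene ADM (2.20-fold up).

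For lineage transcription factors the counts in L3.6pl were 8 risen and 11 fallen of 29, for classical progenitor genes 7 and 6 of 34, and for epithelial junction genes 5 and 6 of 30. BET and P-TEFb genes had 6 risen and 2 fallen of 14, with HEXIM1 and BRD2 (2.31-fold) risen, and KDM6A, COMPASS and Polycomb genes had 5 and 7 of 25. Of 34 G2 and mitosis genes 8 rose and 7 fell, with FOXM1 down 2.07-fold, and of 24 apoptosis regulators 8 rose and 6 fell. YAP and TEAD targets had 10 risen and 5 fallen of 23, MAPK output genes 8 and 10 of 22, cholesterol genes 8 and 6 of 24, and ATF4 genes 12 and 4 of 27. Of 41 ribosomal protein genes 1 rose and 2 fell. Stromal and endothelial markers had 5 risen and 1 fallen of 21, immune markers 5 and 2 of 22, and acinar and endocrine markers 3 and 0 of 19. Adjusted over the list alone, these counts moved by at most 3 genes. Median, mean and test differed in sign for 8 lists, namely classical, transcription factor, mitosis, apoptosis, inflammatory, interferon, epithelial and cholesterol genes. Without L3.6pl_DMSO replicate 2 or L3.6pl_JQ1 replicate 2 the number of risen genes in L3.6pl was 2604 or 2545.

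**Figure D2:**
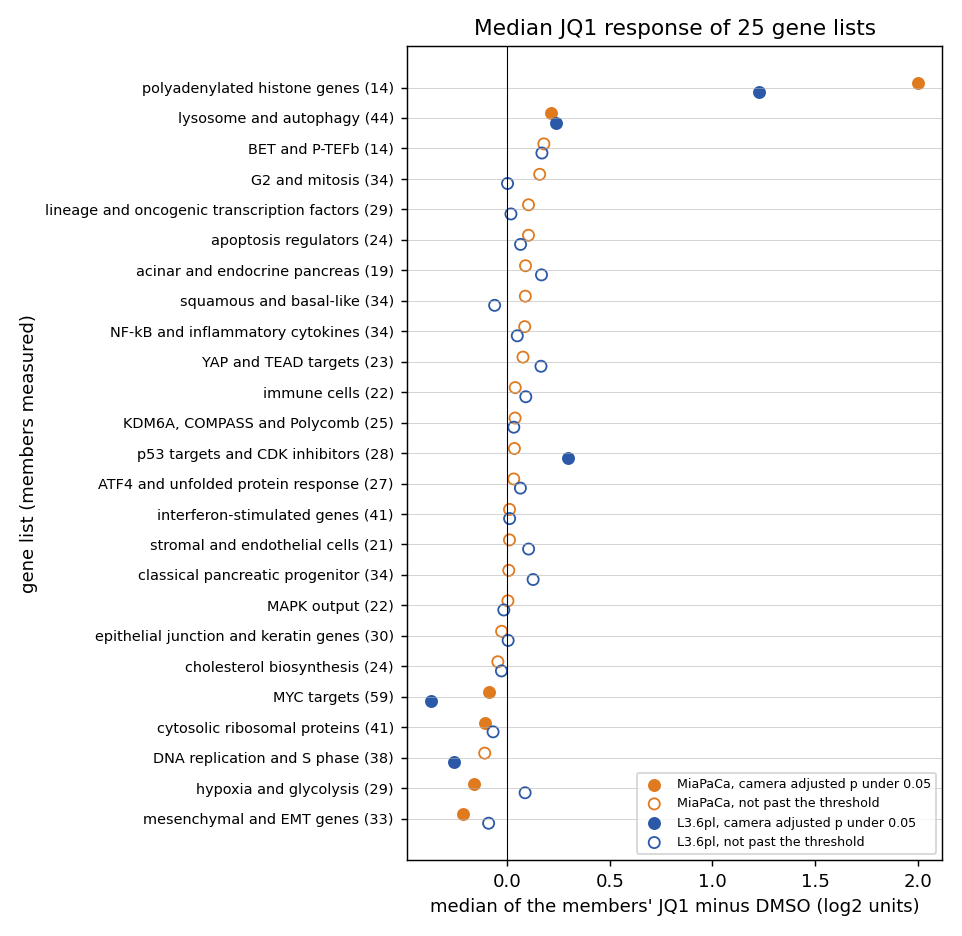
Median log2 change under JQ1 (x axis, JQ1 minus DMSO) of the members of each of 25 gene lists (y axis, members measured in parentheses) in MiaPaCa and L3.6pl. Filled points passed camera with the preset correlation; histone genes have the highest medians in both lines, 2.003 and 1.23, and no list passed with an estimated correlation.

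Both lines shared a large part of the response to JQ1. Among risen genes, HIST1H2BC (3.65 and 2.81 log2 units in MiaPaCa and L3.6pl), EFR3B (2.51 and 2.58), HIST1H2AE (2.42 and 2.46), HIST1H2AG (2.72 and 2.37) and SERPINI1 (4.08 and 2.31) had the largest shared rises, ranked by the smaller of both changes. HIST1H2BC was measured only by probe sets with a cross-hybridization suffix. Among fallen genes, GSAP changed by -2.82 and -3.79, the export pump gene ABCC2 by -2.79 and -3.12, TPRG1 by -2.67 and -3.39, MIG7 by -2.69 and -2.54, and KCTD15 by -2.42 and -3.16. In all, 1866 genes rose in both lines, against 746 expected of independent lists (odds ratio 6.99, Fisher's exact test, two-sided p at most 1e-300). A further 2155 fell in both, against 702 expected (odds ratio 13.5, Fisher's exact test, two-sided p at most 1e-300). Of the 4378 genes called in both lines, 4021 (91.8%) shared their direction and 357 did not. Of these, 204 rose in MiaPaCa and fell in L3.6pl, against 699 expected (Fisher's exact test, two-sided p = 1.36e-146), and 153 did the opposite, against 749 expected (Fisher's exact test, two-sided p = 3.84e-210). Genes too dim to be called in either line were kept, which can raise an overlap above that of independent lists. Fisher's test also takes genes as independent, so these p-values may overstate the evidence. Across genes, the 2 responses correlated with Pearson's r of 0.56 and Spearman's rank correlation of 0.52, and genes are not independent replicates. Among genes at or above the median level, Pearson's r was 0.68.

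**Figure D3:**
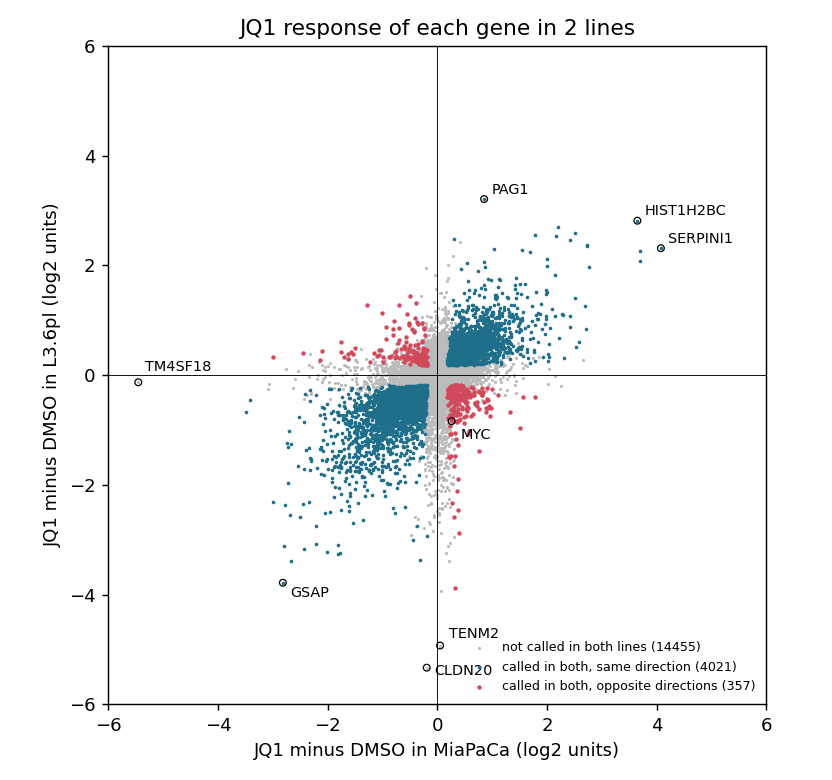
JQ1 minus DMSO in log2 units for each of 18833 genes in MiaPaCa (x axis) and L3.6pl (y axis). Each point is a gene; 4021 genes called in both lines share their direction, 357 do not, and TM4SF18, CLDN20 and TENM2 lie close to an axis.

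The test of the difference between lines asked which genes responded to JQ1 differently in L3.6pl and MiaPaCa. MYC differed, with a rise in MiaPaCa, a fall in L3.6pl and a difference of -1.10 ± 0.10 SE log2 units (n = 2 arrays per group, adjusted p = 0.000432). CLDN20 (-5.14), TENM2 (-4.98), TMEM100 (-4.001) and NPR3 (-3.60) were among the most negative differences. In DMSO-treated MiaPaCa, CLDN20, TENM2 and NPR3 were below the background bound and TMEM100 lay 0.016 log2 units above it. TM4SF18 (5.32), GLDC (3.32), PDE10A (2.95), HOXC8 (2.92) and SERPINA3 (2.86), which encodes a secreted protease inhibitor, had the most positive differences. These 5 genes lay between -0.50 and 0.31 log2 units from the bound in DMSO-treated L3.6pl. SERPINA3 fell 6.75-fold in MiaPaCa. TENM2 in MiaPaCa read 0.05 with its chosen probe set and -0.31 as the median over all its probe sets. The difference for DNAJC6 was 0.78 with the chosen probe set and -0.13 with the mean of its probe sets, and that for ANO1, which did not pass, was 0.41 and -0.53.

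In all, 4120 of 18833 genes (21.9%) passed this test, 1922 with a more positive and 2198 with a more negative response in L3.6pl. HEXIM1 rose further in L3.6pl (difference 0.70 ± 0.10 SE log2 units, or 0.73 to 1.49 with its 4 other probe sets), and the SERPINI1 response was smaller there (-1.76 ± 0.23 SE). RUNX3 differed by -1.03 ± 0.12 SE, but its probe set above the bound in MiaPaCa gave -0.18 and did not pass. TP63 differed by -0.37 ± 0.11 SE (n = 2 arrays per group, adjusted p = 0.0494). With every probe set tested on its own, the chosen TP63 probe set did not pass the test of the difference (adjusted p = 0.0657). Other TP63 probe sets gave -0.84 and -1.60 and passed, while those with -0.51 and 0.022 did not. CDKN1A (0.56), GATA6 (0.28) and KDM6A (-0.011) did not pass, while the other CDKN1A probe set gave 0.65 and passed when every probe set was tested on its own (adjusted p = 0.0371). Of the genes called in 1 line alone, 1276 of 2671 for MiaPaCa and 1339 of 3360 for L3.6pl passed the test of the difference.

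Of the 25 lists, 5 passed camera for the difference. The DNA replication list was more negative in L3.6pl for 14 of 38 genes and more positive for 2, or 16 and 3 adjusted over the list alone (adjusted p = 0.000146, or adjusted p = 0.2197 with an estimated correlation). CLSPN (-0.91) and CDT1 (-0.68) had the smallest adjusted p of its members. For MYC targets the counts were 20 and 1 of 59, or 25 and 4 adjusted over the list alone (adjusted p = 0.000229, or adjusted p = 0.264 with an estimated correlation), with SORD at -0.87, or 0.046 without suffixed probe sets. Inflammatory genes were more negative in L3.6pl for 12 of 34 and more positive for 2, also adjusted over the list alone (adjusted p = 0.00149, or adjusted p = 0.2197 with an estimated correlation). CXCL3 differed by -2.40, but it was below the background bound in MiaPaCa with both treatments. The chemokine CXCL1 differed by -1.64, with a rise of 0.56 in MiaPaCa and a fall in L3.6pl.

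Polyadenylated histone genes were more negative in L3.6pl, that is less risen, for 9 of 14 and more positive for 1, also adjusted over the list alone (adjusted p = 0.00314, or adjusted p = 0.264 with an estimated correlation). HIST1H2BJ (-1.44) and HIST1H2BD (-1.43) came first by adjusted p, but the HIST1H2BJ probe set without a suffix read -0.060. The call of this list was lost without probe sets with cross-hybridization suffixes (adjusted p = 0.0981). Hypoxia and glycolysis genes were more positive in L3.6pl for 8 of 29 and more negative for 0, also adjusted over the list alone (adjusted p = 0.00418, or adjusted p = 0.265 with an estimated correlation). ADM differed by 2.15 and ENO2 by 1.45, and both fell in MiaPaCa and rose in L3.6pl. The other 20 lists did not pass (adjusted p from 0.0644 to 0.888), and the classical and transcription factor lists differed in sign between median, mean and test. Without L3.6pl_DMSO replicate 2 the number of genes past the test of the difference was 2630.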

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

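The tests of non-hybridizing KDM6A probe sets and of S-phase cells were chosen after the results they use had been seen, and so were the levels of MAOA and CASK; the other tests were not. By the test of the difference, the response to JQ1 differed between lines for 4120 of 18833 genes (21.9%), and for 65 of the 83 named genes. Some named genes were chosen by this same test or for a large change in 1 line. The high share among them was therefore built into the choice. Values below are the L3.6pl response minus the MiaPaCa response in log2 units. A positive value means a larger rise or a smaller fall in L3.6pl, or a rise there beside a fall in MiaPaCa.

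Among the largest changes in MiaPaCa, differences were -1.76 for SERPINI1, -1.43 for HIST1H2BD, -1.62 for HIST1H3H, -0.83 for HIST1H2BC, -0.80 for HIST1H2AC, -0.35 for HIST1H2AG, -1.87 for HIST1H2AD, -1.44 for HIST1H2BJ, -2.37 for ITPR1 and -1.98 for PPP3CA. TM4SF18 differed by 5.32, SEMA3D by 2.81, PDE10A by 2.95, CCDC190 by 2.84, HOXC8 by 2.92, HNMT by 0.69, GLDC by 3.32, SERPINA3 by 2.86 and GSAP by -0.97. Among the largest changes in L3.6pl, differences were 2.35 for PAG1, 0.50 for HIST2H2BE, 0.78 for DNAJC6, 2.17 for ARHGAP29 and 2.02 for FAM46C. CLDN20 differed by -5.14, TENM2 by -4.98, TMEM100 by -4.001, NPR3 by -3.60, SCG2 by -3.05, EHF by -1.44, CEMIP by -3.41 and KCTD15 by -0.74.

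Of the genes fixed in advance, MYC differed by -1.10, HEXIM1 by 0.70, TP63 by -0.37 and RUNX3 by -1.03. Of MYC targets and cell cycle genes, CDK4 differed by 0.47, PPRC1 by -0.69, SORD by -0.87, SLC19A1 by -0.48, FOXM1 by 0.43, CLSPN by -0.91 and CDT1 by -0.68. Of p53 targets and CDK inhibitors, TP53I3 differed by -0.52, CDKN2B by 1.87 and PLK2 by 0.95. Of inflammatory and interferon genes, NFKBIZ differed by -1.64, LIF by -0.89, CXCL3 by -2.40, CXCL1 by -1.64, PARP9 by -1.17 and IFI44 by -1.73. Of mesenchymal, squamous and stromal genes, MYL9 differed by 1.21, COL4A1 by -1.19, AXL by -2.37, KRT15 by 0.75, DSG3 by -3.29 and COL1A2 by 1.70. Of hypoxia and lysosome genes, PDK1 differed by 0.55, PFKFB4 by 0.91, ADM by 2.15, ENO2 by 1.45, SQSTM1 by -0.66, LAMP3 by 1.58 and NEU1 by 0.82. Median differences were -0.70 for polyadenylated histone genes, -0.20 for MYC targets, -0.24 for DNA replication genes, -0.15 for inflammatory genes and 0.11 for hypoxia genes.

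Some of these differences rest on 1 line, since the chosen probe set had no measurable level in the other. With both treatments the chosen probe sets of PAG1, FAM46C, CLDN20, TENM2, NPR3, SCG2, RUNX3, LAMP3, CDKN2B, CXCL3 and IFI44 were below the background bound in MiaPaCa, and SEMA3D, PDE10A, CCDC190, GLDC, SERPINA3 and COL1A2 in L3.6pl. CEMIP and DSG3 were below it in MiaPaCa with DMSO and lay 0.087 and 0.23 log2 units above it with JQ1. TM4SF18 and HOXC8 were below it in L3.6pl with JQ1 but not with DMSO. SERPINI1 does not rest on 1 line, as it was below the bound in MiaPaCa with DMSO but 3.82 log2 units above it with JQ1. Its rise in MiaPaCa is a lower limit. HIST1H2AD rose from below the bound and GSAP fell to below it in both lines, so their differences compare 2 lower limits and do not show a different response. The difference for HIST1H2BJ came from a probe set with a cross-hybridization suffix, and its probe set without one read -0.060. Another RUNX3 probe set was above the bound in MiaPaCa, and its difference was -0.18.

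A first pattern is the set of 1211 genes that fell in L3.6pl and responded differently in MiaPaCa. Absent signal in MiaPaCa would need nearly all of them at the background bound. In DMSO-treated MiaPaCa 32.5% (393 genes) were at or below it. This argues against absent signal as the cause for the remainder and leaves it open for those 393. Of all tested genes 28.8% were at or below the bound there, but these include genes dim in both lines, so the shares are not alike. In the mirror set of 1230 genes that fell in MiaPaCa and responded differently in L3.6pl, 11.7% (144) were at or below the bound in DMSO-treated L3.6pl. With all 8 arrays quantile normalized together, 95.0% of the 1211 stayed past the test in the same direction. Of all 4120 genes past the test, 3777 did so. This argues against the unlike distributions of the lines as the cause. RMA was not rerun on the probes of all arrays together, so its other steps were not tested. Of 696 such genes more than 1 log2 unit above the bound in both lines, 152 rose in MiaPaCa, 197 fell and 347 did not pass. A line-specific dependence on BET proteins may account for these genes, as a hypothesis that was not tested.

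A second pattern is the KDM6A signal below the background bound in MiaPaCa. Probe sets that do not hybridize are argued against by a KDM6A level 4.34 log2 units above the bound in L3.6pl, and a transcript form missed by the chosen probe set by the brighter of 2 probe sets, which lay -1.35 units from the bound in MiaPaCa. A loss reaching the nearest gene with clear signal in L3.6pl on both sides is argued against by KRBOX4, 2.88 units above the bound in MiaPaCa. The nearest measured genes, DUSP21 and CXorf36, were dim in both lines, so a loss that ends between KDM6A and KRBOX4 stays open. On the other side FUNDC1 lay -1.18 and MAOA -0.073 units from the bound in MiaPaCa, against 6.83 and 3.70 in L3.6pl, while CASK, farther out, lay 4.09 above it in MiaPaCa. A loss that spans KDM6A and genes on that side without reaching KRBOX4, or silencing, may explain this, and neither was tested with DNA.

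The last pattern is the rise of polyadenylated histone genes. Cross-hybridization between near-identical histone genes cannot be told apart for the list as a whole. Of the 10 probe sets without a cross-hybridization suffix, 6 rose in MiaPaCa and 5 in L3.6pl. Those of HIST1H2BD read 3.70 and 3.12 log2 units in MiaPaCa and 2.27 and 2.11 in L3.6pl. At the other end, that of HIST1H1E read -0.24 and -0.052 in the respective lines. The 10 probe sets without a cross-hybridization suffix had a median of 1.199 in MiaPaCa and 0.59 in L3.6pl. Both lie above the 0.5 that would have argued against it. The prediction fixed before the results used these medians alone, and the intervals that follow were not part of it. However, the 97.9% sign-test intervals, 0.12 to 3.12 in MiaPaCa and 0.087 to 2.27 in L3.6pl, take that limit in. They treat the 10 probe sets as independent, although these come from 7 genes, so they may be too narrow. More cells in S phase as the cause cannot be told apart in either line. In L3.6pl the S-phase list fell (camera adjusted p = 2.84e-06, or 0.0985 with an estimated correlation, and adjusted p = 8.56e-05 with fry's directional test). In MiaPaCa that list did not pass camera (adjusted p = 0.347) but was shifted down by fry's directional test (adjusted p = 0.0169). There 14 of its 38 genes fell and 10 rose. The list as a whole thus did not rise in either line. These are transcript levels, which JQ1 may lower by itself, so they do not measure the share of cells in S phase. A direct effect of BET inhibition on these genes stays open and was not tested.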

How the results depend on the processing

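The setting without suffixed probe sets was chosen after seeing the data, the others before. Of the list results under the alternatives, 1039 kept their side of the threshold, 58 passed it newly and 28 no longer did. No list that passed both with the reported setting and with an alternative turned its direction, but some lists that passed with neither did. Of the named gene results, 4550 kept theirs, 59 passed newly, 190 no longer did and 11 turned. With any 1 array left out, at least 5376 of 7049 genes in MiaPaCa, 5235 of 7738 in L3.6pl and 2539 of 4120 for the difference kept call and direction. Counts were within 1.5 times of the reported ones except as follows, and the cause was not tested unless named.

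A threshold of 1 log2 unit, stricter by construction, left 1139 genes in MiaPaCa (371 risen, 768 fallen), 907 in L3.6pl (227, 680), 741 for the difference (301 more positive, 440 more negative) and 374 in both lines (97 risen, 277 fallen). Among genes at or above the median level r between the responses was 0.68. With estimated correlations 0 lists passed in each contrast, where 8, 10 and 9 had an unadjusted camera p under 0.05 with the preset one. With fry's directional test 17, 18 and 16 passed in MiaPaCa, L3.6pl and the difference, and with its mixed test 24, 25 and 25, because fry does not compare lists with other genes. With a filter at the 25th percentile or without suffixed probe sets 3 lists passed in MiaPaCa. With quantile normalization of all arrays 9 passed in L3.6pl and 8 for the difference.

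The squamous list passed as fallen in L3.6pl with the mean of probe sets (adjusted p = 0.0228), with quantile normalization (adjusted p = 0.0395), without suffixed probe sets (adjusted p = 0.0326), with fry's directional test (adjusted p = 0.000775) and without L3.6pl_DMSO replicate 2 (adjusted p = 0.0422) or L3.6pl_JQ1 replicate 2 (adjusted p = 0.0476). For the difference it passed as more negative in L3.6pl with several alternatives. Among them were the mean of probe sets (adjusted p = 0.0157), quantile normalization (adjusted p = 0.0492) and fry's directional test (adjusted p = 0.00284). The interferon list passed with the mean of probe sets as fallen in L3.6pl (adjusted p = 0.0143) and as more negative there (adjusted p = 0.0279). It also passed as more negative with quantile normalization (adjusted p = 0.0492). The epithelial list passed as fallen in MiaPaCa without MiaPaCa_DMSO replicate 1 (adjusted p = 0.0190), and as more positive in L3.6pl without that array (adjusted p = 0.0388) or with quantile normalization (adjusted p = 0.0492). Among other lists, the inflammatory one passed as fallen in L3.6pl with quantile normalization (adjusted p = 0.0494) and without L3.6pl_JQ1 replicate 2 (adjusted p = 0.0293).

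With 1 array left out, which loses a residual degree of freedom and assumes that the lone array varies like the others, counts were 5552 to 6818 in MiaPaCa (2729 to 3385 risen, 2823 to 3433 fallen) and 5437 to 7612 in L3.6pl (2545 to 3931 risen, 2886 to 3681 fallen). For the difference they were 2630 to 3148 (1204 to 1486 more positive, 1426 to 1745 more negative), and in both lines 3173 to 3585. The risen count in L3.6pl was lowest without L3.6pl_JQ1 replicate 2 (2545) and L3.6pl_DMSO replicate 2 (2604). Lists passing numbered 5 to 7, 4 to 8 and 5 to 6, the highest for L3.6pl without L3.6pl_JQ1 replicate 2.

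Some genes turned with the choice of probe sets. Without suffixed probe sets PAG1 had -0.042 in MiaPaCa, RPL3 0.48 in MiaPaCa and 0.62 in L3.6pl, SORD 0.028 in L3.6pl and 0.046 for the difference, and ANO1 -1.69 for the difference. With the mean of probe sets the difference was -0.53 for ANO1 and -0.13 for DNAJC6. As the median over all probe sets of the gene it was -0.31 for ANO1 and -0.47 for DNAJC6, and TENM2 had a median of -0.31 in MiaPaCa.

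The replicate numbers were treated as names only. Deviations of same-numbered arrays correlated at 0.085 in MiaPaCa and -0.012 in L3.6pl, so no strong shared shift was seen. With 2 arrays per group this cannot exclude that same-numbered arrays were paired. With the replicate block 6670, 7332 and 3279 genes were called in MiaPaCa, L3.6pl and the difference, the p53 list in L3.6pl no longer passed (adjusted p = 0.0562) and the interferon list passed for the difference (adjusted p = 0.0427). Signal over background limits the genes near the bound, such as SERPINI1 in MiaPaCa, whose folds are lower limits.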

Other observations

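In an exploration of 1065 Gene Ontology terms of 15 to 299 genes, chosen after the lists had been tested, genes of mitochondrial protein synthesis stood out in both lines. Of 101 genes of mitochondrial translation, 61 fell and 10 rose under JQ1 in MiaPaCa (median -0.29 log2 units, camera adjusted p = 5.99e-07, or adjusted p = 0.993 with an estimated correlation). In L3.6pl 63 fell and 7 rose (median -0.28, camera adjusted p = 4.62e-09, or adjusted p = 0.834 with an estimated correlation). Of 105 genes of the respiratory electron transport chain, 58 fell and 12 rose in MiaPaCa (camera adjusted p = 6.97e-06, or adjusted p = 0.993 with an estimated correlation), and 41 fell and 10 rose in L3.6pl (camera adjusted p = 0.00574, or adjusted p = 0.836 with an estimated correlation).

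Terms of RNA processing passed camera as shifted down in L3.6pl. Of 114 genes of rRNA processing, 57 fell and 7 rose (camera adjusted p = 3.02e-07), and of 125 genes of tRNA processing 60 fell and 9 rose (camera adjusted p = 2.97e-05), both with adjusted p = 0.834 with an estimated correlation. Of 41 genes of membrane fusion 22 rose and 3 fell in L3.6pl (camera adjusted p = 0.00858, or adjusted p = 0.834 with an estimated correlation). In all, 9 terms passed camera as risen and 21 as fallen in MiaPaCa, and 5 and 31 in L3.6pl. For the difference between lines 0 terms passed, and with an estimated correlation 0 passed in each contrast.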
